A study of Arabidopsis thaliana with 4 samples.

How the data were processed

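RNA was sequenced from the stem base of WT and mol1-1 plants, with 2 libraries per genotype. Per the labels, plants grew for 3 weeks in short days of 8 h light before long days of 16 h light, and polyadenylated RNA was selected before library preparation. The files deposited for each library give read counts per locus in several columns, and per the file headers these are total and unique reads in exons, total and unique reads in genes, exon-exon junction reads and intron reads. The build TAIR10 is named in the submitters' processing notes, while the aligner, the counting program, the use of strand and any read filter are not given in the sources used here. The RPKM values the authors deposited equal total exon reads per kilobase of exon per 1000000 total gene reads of the library, to within a relative difference of 2.15e-14. They were not tested, and all tests used the total exon reads.

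Each file held 33323 rows. The 5 rows without a locus name held 0.0586% to 0.0864% of exon reads and were left out of library sizes and tests. The 2 loci listed more than once were summed, which gave 33316 loci, of which 32828 matched a locus in the reference table of assembly TAIR10.1. That table supplied symbols only. Coordinates are printed for MOL1 alone, from the annotation of TAIR10.1, whose exons for this gene total 3176 bp against 3070 bp in the deposited files. For 6118 loci the files list no annotated transcript and hence no exon reads. Unique reads made up 96.9% to 97.1% of exon reads. These shares are over all loci, and a gene that shares reads with close copies can have a lower share of its own. Without stated strand use, overlapping and antisense genes cannot be told apart.

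Total exon reads in named loci were 30794836, 28017346, 37059413 and 28570901 in WT replicates 1 and 2 and mol1-1 replicates 1 and 2. The replicates of each genotype differed by more than sampling noise, with a chi-square per degree of freedom of 28.9 between the WT libraries and 62.3 between the mol1-1 libraries, so each library counted as 1 sample. The common biological coefficient of variation was 16.5%.

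Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr by genotype, which kept 19024 genes. Libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit and glmQLFTest) compared the genotypes with no covariate. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. CPM values use the TMM-scaled library sizes, and log2 fold changes are mol1-1 over WT. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic.

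Before the data were examined, 23 gene lists with 422 members were fixed by locus. They covered cambium regulators, xylem and secondary wall, lignin, phloem, ethylene synthesis and signalling, ethylene response factors, jasmonate, touch and wounding, salicylate and defence, auxin, cytokinin, gibberellin, strigolactone, brassinosteroid, abscisic acid, cell division, photosynthesis, epidermis and cuticle, floral organ identity, circadian clock, glucosinolates, flavonoids and heat shock. Lists with at least 5 tested members, 22 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and p-values were adjusted over these lists. The rule for named genes was fixed at the same time. It takes MOL1, up to 10 genes per direction with the largest fold change among genes passing with a mean of at least 1 CPM and both mutant libraries on the same side of both WT libraries, and up to 3 passing members per list with the smallest p. Where no member of the cambium, ethylene synthesis or jasmonate lists passed, the 2 members with the smallest p are given as values.

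Alternatives were DESeq2 1.42.0, limma-voom, RLE, upper-quartile or no scaling, no filter or a filter at 1 CPM in 2 libraries, a test against a fold of 1.5, the replicate number as a factor, each library left out in turn, and unique exon or total gene reads in place of total exon reads. For the lists they were an estimated correlation, ranks and fry. At the preset correlation camera takes its degrees of freedom from the number of genes, and with an estimated correlation from the libraries. List p-values at the preset correlation therefore do not rest on the number of libraries. A correction for GC content and exon length, a crossed pairing and a newer edgeR dispersion setting were added after seeing the data. The correction used splines with 5 degrees of freedom, and 99.8% of the tested genes had a GC value. In list tests it was applied to log2 CPM, whereas the main list test took the counts. Those tests thus differ in more than the correction. With 3 libraries in a leave-one-out fit, the lone library is assumed to vary like the other genotype.

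The scripts were tested on simulated data with the means, library sizes and dispersions of these libraries, in 5 draws of 19024 genes with 200 genes changed. For the comparison of mol1-1 with WT, 61.5% of genes changed 2-fold, 91.9% of those changed 4-fold and 97.9% of those changed 8-fold were called in the right direction, and 11.0% of the calls fell on unchanged genes. A list of 14 genes shifted 2-fold was called in 5 of 5 draws. Genes were drawn independently, so these draws leave out correlation within lists. In the libraries it was estimated at 0.96 for the lignin list and -0.006 for the touch and wound list. Tables were handled with Python 3.11.15 and pandas 2.3.3.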

Results

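Gene expression was measured by RNA sequencing of polyadenylated RNA from the base of the inflorescence stem of Arabidopsis thaliana. Wild-type plants (WT, accession Col-0) were compared with the mutant mol1-1, and each genotype has 2 libraries. MOL1 (MORE LATERAL GROWTH1) encodes a leucine-rich repeat receptor-like kinase known to restrain secondary growth, the thickening of the stem by the cambium. Each sample was 1 cm of stem next to the rosette, from plants 15 to 20 cm tall. Reads in exons of named loci numbered 30794836 and 28017346 in WT replicates 1 and 2, and 37059413 and 28570901 in mol1-1 replicates 1 and 2. The comparison asks which transcripts depend on MOL1 in this tissue.

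MOL1 (AT5G51350) was lower in both mutant libraries. Its level was 29.6 ± 0.0383 CPM (counts scaled to a library of 1000000 reads; SD, n = 2) in WT and 9.34 ± 0.236 (SD, n = 2) in mol1-1. It fell by 1.66 on the log2 scale (SE 0.12), with an adjusted p of 0.0217 in edgeR's quasi-likelihood test. The raw counts were 938 and 825 in WT against 342 and 264 in the mutant. The gene lies on chromosome 5 from 20867599 to 20870848, on the minus strand, in the RefSeq annotation of TAIR10.1. Its 2 annotated exons span 20868245 to 20870848 and 20867599 to 20868170. A count over the whole gene cannot separate a full-length from a truncated transcript.

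The mutant differed from WT mainly by genes that were higher. Of 19024 genes tested, 38 passed an adjusted p of 0.05, of which 36 rose and 2 fell in mol1-1. Among the 36 were 5 ethylene response factor genes and 4 genes of rapid touch and wound responses, and the median log2 fold change of the 36 was 2.13. All 38 had both mutant libraries on the same side of both WT libraries. MOL1 itself and UBC11 (AT3G08690), which encodes a ubiquitin-conjugating enzyme, were the 2 that fell.

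Among the genes that passed, the largest rise was that of AT1G07135, a gene without a symbol in the reference table. It went from 2.41 ± 1.31 CPM (SD, n = 2) in WT to 38.1 ± 3.36 (SD, n = 2) in mol1-1 (adjusted p 0.0341). TCH4 (AT5G57560), a touch-induced gene for a xyloglucan-modifying cell wall enzyme, rose by 3.93 on the log2 scale (SE 0.26, adjusted p 0.0213), from 5.10 ± 1.88 to 78.0 ± 3.59 CPM (SD, n = 2 each). The transcription factor genes ERF105 (AT5G51190) and ERF6 (AT4G17490) rose by 3.78 (SE 0.28) and 3.45 (SE 0.18), both with an adjusted p of 0.0213. SEN1 (AT4G35770), a gene induced by darkness and senescence, rose by 3.32 (SE 0.22), from 1.14 and 1.01 CPM in the WT libraries to 9.73 and 11.9 CPM in the mutant libraries. AT4G27280, which the annotation calls a calcium-binding EF-hand protein, rose by 3.18 (SE 0.23), and AT4G29780, annotated as a nuclease, by 3.07 (SE 0.28). AT1G72920 rose by 2.93 (SE 0.20). The stress-induced zinc finger gene ZAT12 (AT5G59820) rose by 2.81 (SE 0.27), and ERF5 (AT5G47230) by 2.78 (SE 0.29). UBC11 fell by 1.34 (SE 0.12), from 38.6 ± 0.797 to 15.3 ± 0.349 CPM (SD, n = 2 each), with an adjusted p of 0.0341.

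**Figure D1:**
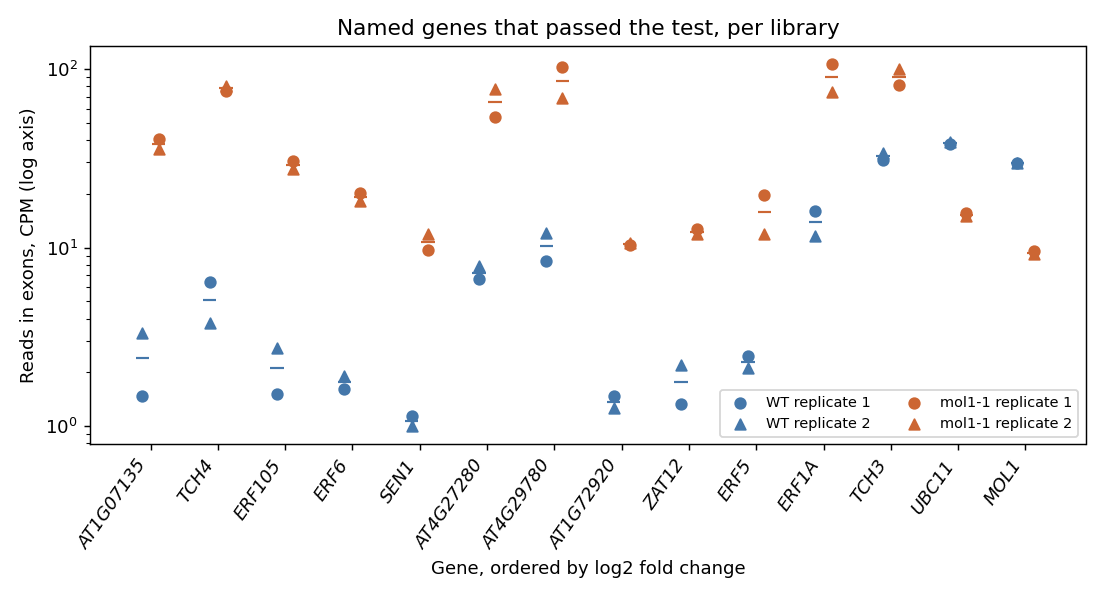
Reads in exons as CPM on a log axis for the 14 named genes that passed the test. Points are libraries (circles replicate 1, triangles replicate 2), and short lines are means of n = 2. WT and mol1-1 points do not overlap for any of these genes, which the naming rule required of the largest rises and falls.

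The count of 38 moved with the method and with single libraries. It was 281 with DESeq2, 141 with no filter on low counts and 11 in a test against a fold of 1.5, and 89, 409 and 212 without WT replicate 2, mol1-1 replicate 1 and mol1-1 replicate 2. Without WT replicate 1 it was 37, with 24 of the 38 among them. With a correction for GC content and exon length, chosen after seeing the data, the adjusted p was 0.0512 for AT1G07135, 0.0512 for ERF1A, 0.0554 for ZAT12 and 0.0614 for ERF5. Their log2 fold changes were then 3.89 (SE 0.40), 2.64 (SE 0.27), 2.73 (SE 0.30) and 2.74 (SE 0.31), against 3.996 (SE 0.35), 2.71 (SE 0.25), 2.81 (SE 0.27) and 2.78 (SE 0.29) without it. Each fold moved by less than its SE, and the calls ended with slightly smaller folds and larger SEs. Unadjusted p was under 0.05 for 1130 genes, where 951 would be reached by chance alone. The p-values of single genes measure the spread between these libraries, since nothing in the labels says whether replicates came from separate pools of plants.

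Genes that respond within minutes to touch and wounding were higher as a group. Of the 23 tested members of the rapid touch and wound list, 22 had a log2 fold change above 0, and the median was 1.49. Over all genes 4 members passed, all of them higher, and 21 passed when adjusted over the list alone. Camera gave the list an adjusted p of 1.74e-70 at the preset correlation, and with an estimated correlation the adjusted p = 0.0555. The estimated correlation was -0.006, below the preset 0.01, so correlation between members does not account for the larger p. TCH4 and ZAT12 were the members with the smallest p. TCH3 (AT2G41100), a calmodulin-like gene, rose by 1.49 (SE 0.16, adjusted p 0.0493), from 32.4 ± 2.17 to 90.7 ± 13.5 CPM (SD, n = 2 each). Without WT replicate 1 or WT replicate 2 the adjusted p of TCH3 was 0.131 or 0.0726, and that of UBC11 was 0.055 or 0.0594. With a filter at 1 CPM that of TCH3 was 0.0521.

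Ethylene response factor genes formed the list with the highest median. The median log2 fold change over 14 tested members was 2.72, and 13 were above 0. Over all genes 5 members rose and none fell, and 13 passed when adjusted over the list alone, of which 12 were higher. The adjusted p was 2.70e-61 by camera, and with an estimated correlation the adjusted p = 0.0833. The members with the smallest p were ERF6, ERF105 and ERF1A (AT4G17500). ERF1A rose by 2.71 (SE 0.25, adjusted p 0.0367), from 13.8 ± 3.17 to 90.4 ± 22.8 CPM (SD, n = 2 each). The adjusted p of ERF5 was 0.0492, and it was 0.11 with limma-voom and 0.0521 with a filter at 1 CPM.

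The list of ethylene synthesis and signalling genes gave no call (camera adjusted p 0.267), and its median over 16 tested members was 0.03. With the correction for GC content and exon length, run on log2 CPM in place of counts, camera called it higher (adjusted p 0.0116). The list was not tested on uncorrected log2 CPM, so the call cannot be credited to the correction alone. No member passed over all genes, and 1 passed when adjusted over the list alone. ACS6 (AT4G11280), which encodes an enzyme of ethylene synthesis, had 5.36 ± 1.06 CPM in WT and 21.9 ± 5.85 in mol1-1 (SD, n = 2 each). Its log2 fold change was 2.03 (SE 0.25, adjusted p 0.0663), and the adjusted p was 1.81e-09 with DESeq2, 0.00946 with no filter, and 0.0284, 0.00247 and 0.00842 without WT replicate 2, mol1-1 replicate 1 and mol1-1 replicate 2. ACS8 (AT4G37770), of the same enzyme family, had a log2 fold change of 0.91 (SE 0.44, adjusted p 0.929).

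Jasmonate synthesis and signalling genes had a median log2 fold change of 0.35 over 30 tested members. The camera call was higher in mol1-1 with an adjusted p of 0.028, and with an estimated correlation the adjusted p = 0.905. No member passed over all genes or when adjusted over the list alone. JAZ7 (AT2G34600), a repressor gene induced by jasmonate, had 0.347 and 0.252 CPM in WT, and 19.8 and 2.68 CPM in mol1-1 replicates 1 and 2 (adjusted p 0.292). Its adjusted p was 0.00622 with DESeq2, 0.0274 without mol1-1 replicate 1 and 8.90e-05 without mol1-1 replicate 2. AOC3 (AT3G25780), an allene oxide cyclase gene of jasmonate synthesis, had 10.4 and 6.90 CPM in WT, and 61.8 and 15.1 CPM in mol1-1 (adjusted p 0.57, or 0.000851 without mol1-1 replicate 2). The list's adjusted p was 0.0721 by ranks, 0.817 without mol1-1 replicate 1 (median -0.08), and 0.248 in the opposite direction without WT replicate 2, where the median was 0.13.

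Regulators of the cambium showed no shift as a group. The median over 32 tested members was -0.01, with 16 above and 16 below 0, and the camera adjusted p was 0.469. The member with the smallest p was TMO5 (AT3G25710), a vascular transcription factor gene, with a log2 fold change of -0.40 (SE 0.13, adjusted p 0.638). SMXL4 (AT4G29920), known from phloem formation, had -0.43 (SE 0.17, adjusted p 0.796). The lists for xylem and secondary wall (median 0.03, camera adjusted p 0.62), lignin monomer synthesis (-0.15, 0.108), phloem (-0.06, 0.75) and cell division (-0.07, 0.596) gave no call either, and no member of these lists passed. On simulated counts for this comparison, 61.5% of genes changed 2-fold and 91.9% of those changed 4-fold were recovered among 19024 genes. These draws held 200 changed genes and drew genes independently, so the shares may be too high for the libraries. In the libraries the smallest log2 fold change that passed was 1.23 among rises and -1.34 among falls. A 2-fold change of a single cambium or vascular gene may therefore have been missed. The xylem list was called when 1 library was left out, as lower without WT replicate 1 (adjusted p 0.0386) and as higher without WT replicate 2 (0.00357) or mol1-1 replicate 2 (0.000874). The lignin list was called lower by ranks (adjusted p 0.0227). Its median was -0.33 without WT replicate 1, -0.02 without WT replicate 2 and -0.59 without mol1-1 replicate 1, but 0.15 without mol1-1 replicate 2. The cell division median was 0.05, -0.23, 0.04 and -0.25 in the same order.

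Genes of the epidermis and cuticle were lower as a group in mol1-1. The median log2 fold change over 15 tested members was -0.47, with 14 below 0 and a camera adjusted p of 2.11e-06. No member passed over all genes or over the list alone, and with an estimated correlation the adjusted p = 0.42. Flavonoid synthesis genes had a median of -0.90 over 13 tested members and a camera adjusted p of 3.94e-06, and with an estimated correlation the adjusted p = 0.889. That median was -0.25 without WT replicate 1 and -1.39 without WT replicate 2. The median deviation of the flavonoid list from the 4-library mean was 1.05 in WT replicate 1, against -0.18 in WT replicate 2 and -0.47 and -0.32 in mol1-1. Photosynthesis genes had a median of 0.22 over 24 members, with a camera adjusted p of 0.0244, and with an estimated correlation the adjusted p = 0.905. With the correction for GC content and exon length, run on log2 CPM in place of counts, the camera adjusted p was 0.588 (median 0.12). The photosynthesis median was 0.42 without mol1-1 replicate 1, and 0.22 and 0.24 without WT replicates 1 and 2. Without mol1-1 replicate 2 it was 0.03, still above 0, though camera's direction was the opposite. The median deviation of this list from the 4-library mean was 0.33 in mol1-1 replicate 2, against -0.09 in mol1-1 replicate 1 and -0.11 in each WT library.

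**Figure D2:**
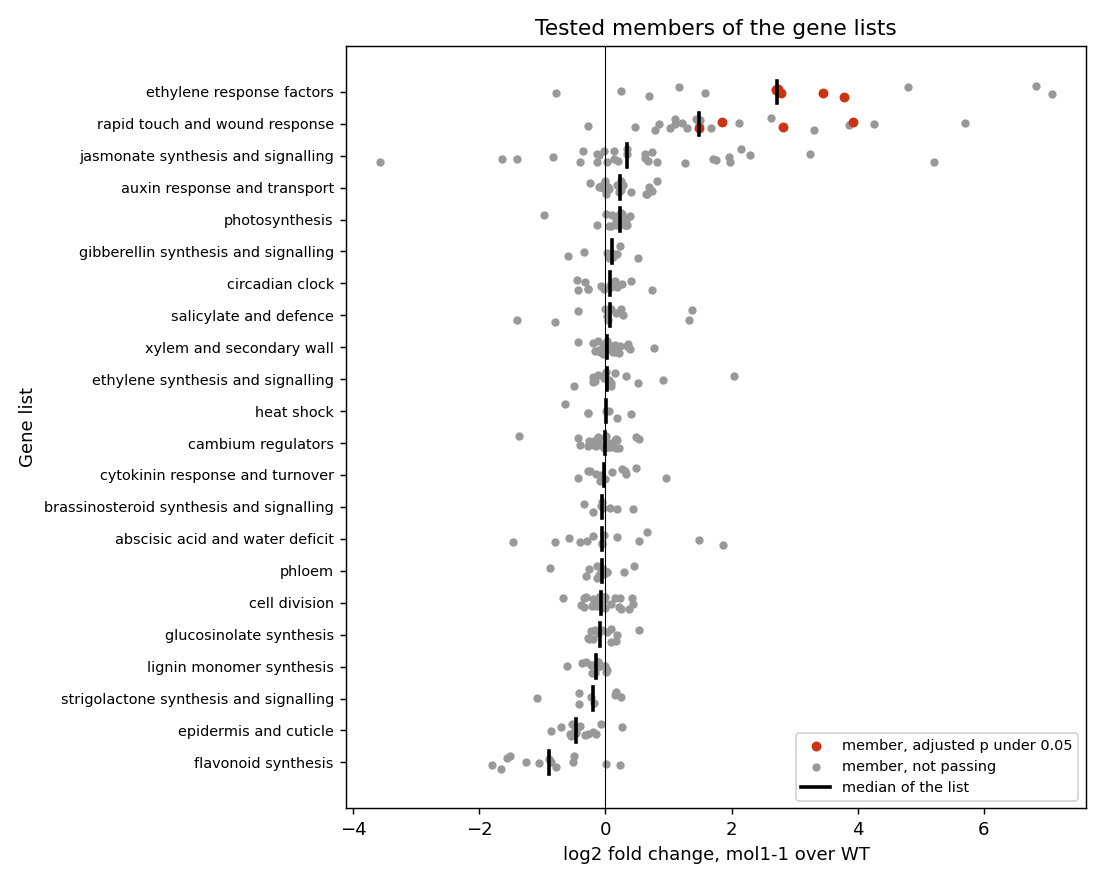
Log2 fold change of mol1-1 over WT for each tested member of the 22 lists with at least 5 tested members, 1 point per gene, with list medians as black bars and genes passing an adjusted p of 0.05 in red. The touch and wound list (median 1.49) and the ethylene response factors (median 2.72) lie to the right, and flavonoid synthesis (median -0.90) lies to the left.

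Lists for other hormones and states gave no camera call. The adjusted p was 0.0585 for auxin response and transport, which was called higher by ranks (0.00749), with no filter (0.0322) and without WT replicate 2 (0.0228) or mol1-1 replicate 1 (0.00115). It was 0.0585 for salicylate and defence, called higher without WT replicate 1 (0.0323) or mol1-1 replicate 2 (0.00473). It was 0.108 for strigolactone, called lower without WT replicate 2 (0.00357). The other values were 0.75 for cytokinin, 0.778 for gibberellin, 0.75 for brassinosteroid and 0.75 for abscisic acid and water deficit. Heat shock and glucosinolate synthesis genes each gave 0.75. Circadian clock genes gave 0.958, but the list mixes dawn and evening genes, so a test for a shift in 1 direction does not measure a change of phase. For cytokinin (median -0.03), abscisic acid (-0.06) and heat shock (0.01) the median and camera's direction had opposite signs. Among floral organ identity genes 1 was tested, too few for a list test.

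**Figure D3:**
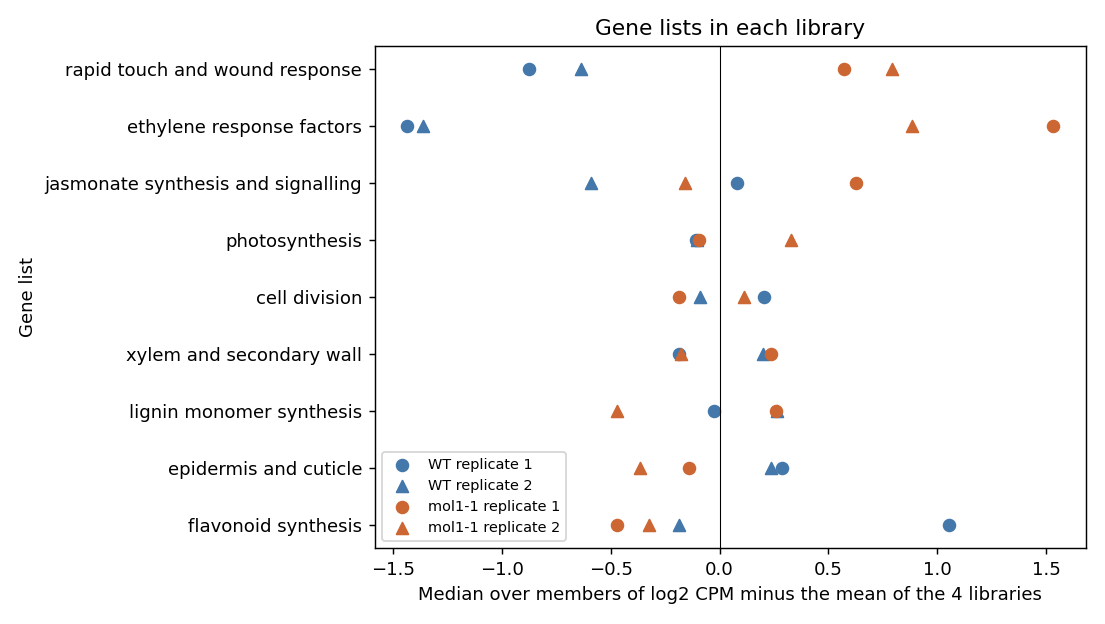
Median over list members of log2 CPM minus the mean of the 4 libraries, 1 point per library (circles replicate 1, triangles replicate 2). For ethylene response factors both WT libraries (-1.44 and -1.37) lie below both mol1-1 libraries (1.53 and 0.88). For lignin synthesis the values are -0.02 and 0.27 in WT replicates 1 and 2, and 0.26 and -0.47 in mol1-1 replicates 1 and 2.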

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

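The files list 6118 loci with no annotated transcript, which carry gene reads but no exon reads and so took no part in the comparison. Of these, 593 had enough gene reads to be tested with edgeR over all loci, and 2 passed, both higher in mol1-1 than in the WT controls. AT5G35935, a pseudogene in the reference annotation, had 1 and 8 gene reads in WT against 807 and 600 in mol1-1, with a log2 fold change of 7.12 (SE 0.47, adjusted p 0.0166). All of these reads were unique. AT2G05914, annotated as a long non-coding RNA antisense to AT2G05915, had 9 and 15 gene reads in WT against 452 and 380 in mol1-1, with a log2 fold change of 4.98 (SE 0.30, adjusted p 0.0166). Its unique reads numbered 8 and 11 against 329 and 263. AT2G05915 had 1 and 2 gene reads in WT and 0 and 2 in mol1-1. No explanation was tested for either locus.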

How the results depend on the processing

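The direction of each named gene held in each fit that tested it. ACS8 was not tested with the 1 CPM filter. RLE, upper-quartile and no scaling, unique exon reads and total gene reads called all 38 genes of the main count again, DESeq2 included them among 281 (253 higher, 28 lower), and no filter among 141 (128 higher, 13 lower). Limma-voom and the 1 CPM filter called 31 of the 38. Against a fold of 1.5, 11 genes passed (11 higher, 0 lower). MOL1, at -1.66, had an adjusted p of 0.054, since that test asks for a fold beyond 1.5. No scaling gave 4 lower genes in place of 2. With 1 library left out the count ran from 37 to 409, with 34 to 285 higher and 3 to 124 lower, and MOL1 kept its call. Without WT replicate 1 or WT replicate 2, 24 or 31 of the 38 were called again, and all 38 without either mutant library. The GC and length correction, chosen after seeing the data, called 31 of the 38 among 39. Except where stated, the cause was not tested.

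The labels number the replicates 1 and 2 in both genotypes without saying that the numbers pair, while names within the deposited tables number the mutant libraries 2 and 3. Deviations of same-numbered libraries correlated at -0.238 across 19024 genes, which are not independent. With a replicate block 136 genes passed (127 higher, 9 lower), and 6 lists, 5 of them among the 6 called without it. Photosynthesis then had an adjusted p of 0.0606, auxin 0.0358, ACS6 0.00392, JAZ7 0.00642 and AOC3 0.0424, and the block changed no other call of a named gene or list. A crossed block, which puts WT replicate 2 with the mutant library so numbered 2 and was chosen after seeing the data, gave 248 genes (218 higher, 30 lower) and called 2 of these 3 named genes.

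With an estimated correlation 0 of the 22 lists passed, and with fry 1, the touch and wound list (adjusted p 0.0331). With 1 library left out, 7 to 9 lists passed. Adjusted p then ran from 0.000874 to 0.0612 for xylem and secondary wall, from 2.08e-36 to 0.817 for jasmonate and from 2.18e-05 to 0.778 for photosynthesis, and each changed direction in at least 1 of these fits. The tested loci are all nuclear, so leaving out organelle genes was not run. At 28017346 exon reads or more per library, 19024 genes had enough counts to be tested.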

Other observations

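The tests of handling, time of harvest, ethylene-induced genes, the epidermal share, segment age and the neighbourhood of MOL1 were chosen only after the values they bear on had been seen, and the extra gene lists and the GC and length correction were added after seeing the data. SEN1, AT1G80440 and MEE14, the last 2 of them chosen after their values were seen, are known to respond to low sugar and were among the genes that rose. A hypothesis is that the mutant stem bases were short of sugar. Other genes known to be induced by sugar starvation were higher as a set. Their median log2 fold change was 0.81, 14 of 15 were above 0 and the camera adjusted p over 3 added lists was 1.40e-21, though none passed alone and with an estimated correlation the adjusted p = 0.0948. DRM2 (1.26), TPS8 (1.28), TPS11 (1.25) and BZIP1 (1.94) had the smallest p among them and were chosen after their values were seen. The sulfate transporter gene SULTR1;2 also rose (log2 fold change 1.98). Of 13 genes known to be induced by sulfur deficit, 7 were tested, and all 7 were above 0, though none passed alone. Their median was 0.58, with a camera adjusted p of 3.86e-08 (0.162 with an estimated correlation). Both sets are in line with the hypotheses that named them.

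Among the 400 tested loci nearest to MOL1 on chromosome 5, 3 passed (WRKY48, AT5G50450 and ERF105, chosen after their values were seen), against 34 of 18623 elsewhere. Fisher's exact test gave a 2-sided p of 0.0423, but these genes prompted the test and 1 of the 3, ERF105, belongs to a list that rose as a group. A linked effect of the mutant locus and chance cannot be told apart from these values.

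Touch, wound and ethylene response factor genes were higher in mol1-1, with a median of 1.67 over 37 members. Dawn minus evening clock genes differed between the genotypes by -0.10 (SE 0.22), so no large change of this index was seen. The index was 1.00 and 1.43 in the WT libraries, so a small shift in time of harvest would not show. An index of this kind can also repeat its value within a day, so another time of harvest is not excluded. Handling that varied from sample to sample stays open. The median gap between replicates of these genes was 0.45 in WT and 0.52 in mol1-1, at percentile 100 of 10000 expression-matched sets in both. The sets were matched on expression alone, and rapidly induced genes may rank high without any handling difference, so this test cannot decide. Handling that differed between the genotypes would not show in gaps between replicates, and the labels give no harvest scheme. Such handling cannot be told apart from an effect of genotype here. The gaps were unsigned. From replicate 1 to 2 the ethylene response factors had medians of -0.35 in WT and -0.28 in mol1-1, and the touch and wound list 0.17 and 0.09. Raised ethylene signalling in mol1-1 also stays open. Ethylene-induced genes outside the pattern had a median of 0.0267 with 70.0% above 0 and a camera adjusted p of 0.138. Most were near 0, such as ETR2 at 0.085 (SE 0.14), ERS1 at 0.005 (SE 0.12), EBF1 at 0.094 (SE 0.15) and EBF2 at 0.049 (SE 0.16). ERF1 (AT3G23240) at 1.17 (SE 0.39) and ARL at 0.647 (SE 0.15) were higher, and PR4 was at -0.32 (SE 0.34). The list of ethylene synthesis and signalling had the same median, 0.0267. An identical value can come from members that both lists hold, so it is not separate evidence. The synthesis and signalling list was called higher only by camera with the GC and length correction (adjusted p 0.0116). That test used log2 CPM in place of counts, so the correction alone cannot be credited.

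Epidermis and cuticle genes were lower in mol1-1. The tables argue against 1 library as the cause, since the median without each library in turn was at most -0.40, and against GC content or gene length, since the corrected median was -0.39. A lower share of epidermis in the mutant segments and lower expression per epidermal cell cannot be told apart here, because the test run, in which 100% of the 10 members with a mean of at least 10 CPM were below 0, only restates the fall of the list.

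Lignin genes were lower in mol1-1 replicate 2 than in replicate 1, by a median log2 ratio of -0.79 over 14 genes. The tables argue against GC content or gene length as the whole cause, as the corrected ratio was -0.66. A younger segment in replicate 2 may account for it, because cell division genes were higher there by a median of 0.36, in 26 of 27 genes. Between the WT libraries the lignin and cell division lists also moved apart, but in the opposite direction, with medians of 0.26 and -0.29 for replicate 2 against replicate 1. In WT all 14 lignin genes and 0 of 27 cell division genes were higher in replicate 2. The higher lignin and lower cell division values thus fell in WT replicate 2 and mol1-1 replicate 1, the libraries paired in the crossed block. Whether the difference goes with that pairing rather than with segment age was not tested.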
